A study of Mus musculus with 3 samples.

How the data were processed

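Liver sections of C57Bl/6 mice, 1 taken 48 h after PBS and 2 taken 48 h after APAP, were measured with 10x Visium. Per the submitters' processing notes the reads were processed with Space Ranger against mm10; the version of Space Ranger and the gene annotation are not given in the sources used here. The deposited values are UMI counts per gene and spot, whole numbers per the file headers, with no normalisation, for the spots called under tissue. Each matrix holds 32285 genes, of which 40 symbols occur more than once; lists and named genes are matched by symbol. The position tables gave the grid place of each spot. Images and their scale factors were not used here. Positions of genes in mm10 were taken from a reference table by symbol.

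The section is the replicate and spots were never tested as replicates. For APAP against PBS, counts were summed over all tissue spots of a section. For regions, spots with at least 500 UMIs were scored by the mean over the score genes of log1p counts per 10000 UMIs, z-scored over the pooled spots of all sections. Within each section the spots were then divided into 3 equal groups by the portal score, or into the top 10% of the LAM score (LAM-high) and the rest, with ties broken by spot order, and counts were summed per section and class. The depth behind each summed library ran from 1485531 to 23194464 UMIs. Genes of a score are left out of the counts of calls for the regions it defines.

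Each comparison was fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F-test with robust dispersion). Section was a block in the region fits, which have separate APAP and PBS coefficients and a test of their difference. Every fit has 1 residual degree of freedom, so the lone PBS section is assumed to vary as the APAP sections do. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 with a standard error derived from the F statistic (the size of the log2 value over the square root of F), CPM values use TMM-scaled library sizes, and a gene with 0 UMIs in PBS is given as a lower bound against 3 UMIs over the section. Counting intervals are exact at 95% and cover counting error only.

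A total of 40 gene lists (cell types, pathways and checks) was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists of a fit, where at least 3 members were tested. Shares of spots were taken after thinning each spot to 1000 UMIs, and a LAM score threshold was set at the 99th percentile of PBS spots. Rings around LAM-high spots count steps on the hexagonal grid. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the tables and figures. Permutation tests over genes used 100000 permutations.

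Named genes followed a rule. For APAP against PBS it takes the 10 highest and 10 lowest log2 fold changes among called genes with at least 10 CPM in the higher group and both APAP sections on the same side of PBS; for each region contrast it takes 8 each way. Mitochondrial, ribosomal and unnamed gene models are left out of these places. It adds fixed genes in every comparison (Trem2, Gpnmb, Spp1, Cd9, Clec4f, Vsig4, Timd4, Cd5l, Adgre1, Ccr2, Cyp2e1, Glul, Cyp2f2, Mki67, Cdkn1a, S100a8, Col1a1 and Alb) and up to 4 members of each list with the largest changes at 5 CPM or more. The comparisons, lists, scores, naming rule and all alternatives but 2 were chosen before the data were examined.

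The alternatives were DESeq2 1.42.0 (Wald test, or its size factors in edgeR), library-size scaling, other filters on low counts and on spot depth, libraries thinned to the smallest, spots weighted alike, genes of mitochondria, ribosomes and haemoglobin left out, no section block, other score definitions and class sizes, camera with an estimated correlation, fry, lists matched on expression (10000 random lists), and each APAP section left out in turn. Added after seeing the data were spots of 8000 to 15000 UMIs and LAM-high spots within the portal-low region. The pipeline was tested on simulated data in which 200 genes per simulation changed 2-fold or 4-fold, some up and some down. Noise was drawn from the fitted dispersions. The data hold more called genes than that, so the shares of false and of recovered calls need not carry over.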

Results

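Spatial gene expression was measured in liver sections of C57Bl/6 mice with 10x Visium, an assay in which a tissue section lies on a grid of barcoded spots and each spot captures RNA from the several neighbouring cells above it. The sections were taken 48 h after phosphate-buffered saline (PBS, 1 section) or acetaminophen (APAP, 2 sections). Acetaminophen is a drug that cytochrome P450 enzymes such as Cyp2e1, concentrated in the hepatocytes around the central veins, convert to a reactive product, and in overdose it kills those hepatocytes. The series title sets the purpose as macrophages in tissue repair, so the comparisons below ask how the injured liver differed from the control, how gene expression differed along the lobule, and which transcripts lay in spots rich in transcripts of lipid-associated macrophages. The PBS section had 1790 tissue spots with 11010574 UMIs and a median of 2798 UMIs per spot. APAP replicate 1 had 1272 spots with 13424330 UMIs and a median of 9860.5. APAP replicate 2 had 2178 spots with 23194464 UMIs and a median of 9987.5. Of the PBS spots, 52.4% held fewer than 3000 UMIs, against 12.5% and 7.35% in APAP replicates 1 and 2. The labels do not say whether the APAP sections came from separate animals, so the spread between them may be technical. The p-values rest mostly on a spread that edgeR shares over genes. The median prior degrees of freedom were 22.9 for APAP versus PBS, 298 for the portal contrast and infinite for the LAM-high contrast. Each fit has 1 residual degree of freedom, so small p-values say little about how each gene varied between sections.

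Whole APAP sections held far more macrophage, matrix and cell cycle transcripts than the PBS section and far fewer transcripts of pericentral hepatocytes. Trem2, a lipid-sensing receptor of macrophages, stood at 2.76 CPM in PBS and 65.6 ± 11.1 CPM in APAP (mean ± SD of TMM-normalised CPM, n = 2), a log2 fold change of 4.57 ± 0.37 (standard error; edgeR adjusted p = 1e-08). Col1a1, a chain of type I collagen, rose, with 11.5 CPM in PBS and 317 ± 62.9 CPM in APAP (log2 fold change 4.79 ± 0.48; edgeR adjusted p = 1.37e-07). Mki67, a marker of cycling cells, rose, with 0.425 CPM in PBS and 49.9 ± 12.6 CPM in APAP (log2 fold change 6.85 ± 0.47; edgeR adjusted p = 2.58e-09). Glul, the glutamine synthetase of the hepatocytes nearest the central vein, fell, with 306 CPM in PBS and 13.6 ± 1.02 CPM in APAP (log2 fold change -4.49 ± 0.32; edgeR adjusted p = 2.58e-09).

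Among the genes with the largest increases, 6 had 0 UMIs in the PBS section and are given as lower bounds, with 3 UMIs over that section as the floor. Adam8, a membrane protease, was at least 59.5-fold higher, Prc1 at least 53.4-fold, Arhgef39 at least 46.4-fold, Pimreg at least 36.9-fold, Hmmr at least 36.8-fold and Nuf2 at least 31.8-fold. Pbk and Ckap2 each had 1 UMI in PBS, and their ratios of APAP to PBS were 189 (33.9 to 7488) and 176 (31.6 to 6979) with 95% counting intervals. Racgap1 had 2 UMIs in PBS and a ratio of 127 (35 to 1048), and Ube2c, a ubiquitin-conjugating enzyme of mitosis, had a log2 fold change of 6.90. Apart from Adam8, these genes are best known from cell division. The largest decreases were those of the glutamate transporter Slc1a2 (-6.24 ± 0.28 on the log2 scale; 60.8 CPM in PBS and 0.784 ± 0.134 CPM in APAP), the ammonium transporter Rhbg (-4.50), Glul, Csad (-3.82), Cyp2c29 (-3.71), Acaa1b (-3.66), Cyp2c37 (-3.50, and -4.15 without APAP replicate 2), Slc17a8 (-3.26), Cyp8b1 (-3.25) and Oat (-3.14). In mm10, Trem2 (ENSMUSG00000023992) lies on chromosome 17 from 48346401 to 48352276, Glul (ENSMUSG00000026473) on chromosome 1 from 153899929 to 153909723 and Slc1a2 (ENSMUSG00000005089) on chromosome 2 from 102658239 to 102790784. All are protein-coding genes.

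Hepatocyte transcripts separated by zone and by pathway. Of the 17 pericentral genes tested, 15 fell and none rose (15 fell adjusted over the list alone), with a median log2 fold change of -2.13. Cyp2e1 had -2.78 ± 0.49 (-3.56 without APAP replicate 2) and Cyp2c29 -3.71 ± 0.40. None of the 12 pan-lobular hepatocyte genes and none of the 12 periportal genes passed the test, over all genes or adjusted over the list alone. edgeR called 3 genes of the 8 of the portal score (1 up, 2 down; 1 up and 3 down adjusted over the list alone). Albumin (Alb) had a log2 fold change of -0.37 ± 0.60 and the periportal P450 Cyp2f2 -0.64 ± 0.42, both short of the threshold (edgeR adjusted p = 0.710 and 0.288). Lipogenesis genes fell in 9 of 10 cases (10 adjusted over the list alone, median -1.86), including malic enzyme Me1 (-2.71), Acacb (-2.71) and Elovl6 (-2.46). Bile acid genes fell in 9 of 12 (9 adjusted over the list alone, median -1.37), including Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-2.19), and Cyp8b1 (-3.25). Fatty acid oxidation genes fell in 6 of 13 (8 adjusted over the list alone, median -1.20), with Ehhadh at -2.53. Cholesterol synthesis genes fell in 5 of 15 (9 adjusted over the list alone, median -0.90), with Insig1 at -1.53. Of 11 mitochondrially encoded transcripts, 9 fell (10 adjusted over the list alone, median -1.39), with mt-Nd3 at -2.41 and mt-Nd1 at -1.98. These 6 lists, pericentral, lipogenesis, bile acid, fatty acid oxidation, cholesterol and mitochondrial, passed camera (camera adjusted p = 4.6e-25, 4.1e-12, 3.59e-08, 4.54e-06, 3.47e-05 and 1.5e-07). At an estimated correlation the camera adjusted p of each was 0.604. That correlation is estimated on 1 residual degree of freedom, so this alternative had little room to call any list, here or below.

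Macrophage transcripts rose across several classes. All 14 pan-macrophage genes rose (14 adjusted over the list alone, median 2.15), including lysozyme Lyz2 (3.63), Cd68 (3.35) and Adgre1, which encodes F4/80 (2.02 ± 0.28). Of the 9 score genes of lipid-associated macrophages, 8 rose (9 adjusted over the list alone, median 3.37), led by Gpnmb (5.79 ± 0.45), Lgals3 (4.85), Trem2 and Capg (3.75). Of 16 further genes of these cells 7 rose (9 adjusted over the list alone, median 0.78), with osteopontin Spp1 at 3.31 ± 0.53 (2.67 without APAP replicate 1) and Lpl at 1.38. Cd9 had 0.73 ± 0.29 and did not pass (edgeR adjusted p = 0.0659). Cd9 passed under 5 alternatives. Over all alternatives the Cd9 adjusted p ran from 0.000652 (edgeR, library-size scaling) to 0.121 (DESeq2). Of 10 Kupffer cell genes, markers of the resident macrophages of the liver, 9 rose (9 adjusted over the list alone, median 1.40): Marco had 3.22 ± 0.32, Cd5l 1.72 ± 0.37, Vsig4 1.65 ± 0.30 and Timd4 1.02 ± 0.30, while Clec4f had 0.58 ± 0.33 and did not pass (edgeR adjusted p = 0.220). Clec4f passed with library-size scaling and with spots weighted alike (0.92 and 0.80; edgeR adjusted p = 0.00217 and 0.0434) and under no other alternative. Cdh5 (1.46), a member of this list, is also a gene of endothelial cells. Monocyte genes rose in 7 of 10 (10 adjusted over the list alone, median 4.01, or 4.01 with 1 gene at its bound), with Chil3 at 5.30 and F13a1, at 0 UMIs in PBS, at least 31.3-fold higher. The chemokine receptor Ccr2 had 4.31 ± 1.07 (3.58 without APAP replicate 1) and did not pass (edgeR adjusted p = 0.103). Ccr2 passed under 6 alternatives, with DESeq2 among them (4.35; DESeq2 adjusted p = 6.87e-08). Over all alternatives the Ccr2 adjusted p ran from 9.48e-21 (edgeR, thinned libraries) to 0.148 (edgeR, DESeq2 size factors). Neutrophil genes rose in 5 of 6 (6 adjusted over the list alone), with a fitted median of 5.13 and 2.46 with the 3 genes at 0 UMIs in PBS set to their bounds. Without APAP replicate 1 the fitted median was 4.42. Csf3r had 2.47 (1.74 without that replicate), and S100a8 had 1.05 ± 0.40 without passing (edgeR adjusted p = 0.0611). S100a8 passed with spots weighted alike and in spots of 8000 to 15000 UMIs (2.21 and 2.15; edgeR adjusted p = 0.000910 and 0.0229) and under no other alternative. Chemokine and cytokine genes rose in 8 and fell in 1 of 15 (9 and 1 adjusted over the list alone, median 1.89), with Ccl6 at 3.77 and Ccl3 at 3.58. These lists passed camera, from 3.04e-17 for pan-macrophage and 2.55e-17 for the LAM score to 2.42e-10 for monocyte, 4.54e-06 for Kupffer cell, 1.52e-05 for chemokine, 0.00226 for neutrophil and 0.0107 for the further LAM genes (camera adjusted p). With an estimated correlation the camera adjusted p of each was 0.604.

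Matrix, stellate and cell cycle genes rose together. Of 16 extracellular matrix and myofibroblast genes, 15 rose (15 adjusted over the list alone, median 3.20), with the protease inhibitor Timp1 at 5.59 and Col1a2 at 4.66. Of 10 stellate cell genes, 6 rose (7 adjusted over the list alone, median 1.20), with Pdgfrb at 1.75. Cell cycle genes rose in 16 of 17 for G1/S (17 adjusted over the list alone, median 3.23) and in all 16 for G2/M (16 adjusted over the list alone, median 5.97). p53 targets rose in 7 and fell in 1 of 13 (7 and 1 adjusted over the list alone, median 0.94), with the cell cycle inhibitor Cdkn1a at 2.93 ± 0.32 and the pro-apoptotic Bbc3, the member that fell, at -1.18. Genes of wound-edge hepatocytes rose in 8 of 12 (9 adjusted over the list alone), with a fitted median of 2.64 and 1.93 with 1 gene at its bound (1.85 fitted without APAP replicate 1). S100a6 had 5.19 and Anxa2 3.51. NRF2 targets, genes of the antioxidant response, rose in 6 and fell in 1 of 16 (6 and 1 adjusted over the list alone, median 1.02, or 1.02 with 1 gene at its bound and 0.42 without APAP replicate 1), with Gsta1 at 2.92 and haem oxygenase Hmox1 at 2.41. The camera adjusted p was 4.61e-25 for matrix, 0.00106 for stellate, 4.27e-20 for G1/S, 3.5e-45 for G2/M, 0.00939 for p53, 3.07e-10 for wound-edge and 0.0114 for NRF2 lists. With an estimated correlation the camera adjusted p was 0.620 for NRF2 and 0.604 for each of the others.

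Sinusoidal endothelial genes rose in 6 of 12 (7 adjusted over the list alone, median 0.73), with Lyve1 at 1.72 and Stab1 at 1.53, and central vein endothelial genes in 3 of 6 (3 adjusted over the list alone, median 1.41), with the Wnt agonist Rspo3 at 1.67. Red blood cell genes rose in 4 and fell in 1 of 5 (4 and 1 adjusted over the list alone, median 3.50), the 4 globin genes being higher. Haemoglobin transcripts took 0.0122% of the UMIs in PBS and 0.150% and 0.224% in APAP. These 3 lists passed camera (camera adjusted p = 0.00594, 0.0295 and 3.26e-05), and with an estimated correlation the camera adjusted p was 0.604, 0.645 and 0.604. No other list passed camera. Counts of genes up and down in them, with those adjusted over the list alone in brackets, were 2 and 0 of 6 (3 and 0) for dendritic cell, 2 and 0 of 8 (2 and 0) for T and NK cell, 0 and 0 of 8 (0 and 0) for B and plasma cell, 0 and 0 of 6 (0 and 0) for portal vessel endothelial, 1 and 0 of 8 (0 and 0) for cholangiocyte and 0 and 0 of 4 (0 and 0) for mesothelial genes. They were 3 and 3 of 12 (3 and 3) for the unfolded protein response, 3 and 2 of 13 (3 and 2) for hypoxia and glycolysis, 2 and 3 of 17 (2 and 4) for acute phase, 5 and 0 of 12 (5 and 0) for efferocytosis, 3 and 1 of 7 (3 and 1) for fetal hepatocyte, 1 and 5 of 13 (1 and 5) for circadian clock, 2 and 2 of 9 (2 and 2) for immediate early and 0 and 0 of 4 (0 and 0) for sex-linked genes. In the acute phase list the serum amyloid genes Saa2 (-2.61, from -3.66 without APAP replicate 2 to -1.99 without replicate 1) and Saa1 (-2.00, and -2.70 without replicate 2) fell while Lcn2 (2.27) and Il1rn (2.33) rose. In the efferocytosis list the phagocytic receptor Axl had 2.03 and the cholesterol exporter Abcg1 2.39. Alpha-fetoprotein Afp had 3.85.

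The edgeR quasi-likelihood test over 13615 genes called 1937 genes higher and 1346 lower in APAP (Benjamini-Hochberg adjusted p under 0.05), and each called gene lay on the same side of PBS in both APAP sections. Scaling by library size alone shifted the median log2 fold change to 0.34 and split the calls 2126 higher and 573 lower (78.8% higher against 59.0%), and DESeq2 called 1193 higher and 675 lower. DESeq2 did not call Cyp2e1, Timd4, Saa1 or Saa2 (DESeq2 adjusted p = 0.0586, 0.137, 0.189 and 0.194), and library-size scaling ended the calls of Bbc3 (edgeR adjusted p = 0.0527) and of the central vein endothelial list (camera adjusted p = 0.0845). A filter of at least 10 CPM in 2 libraries ended the calls of the NRF2 list (median 0.41, camera adjusted p = 0.189) and of Saa2 (edgeR adjusted p = 0.113), and spots of 8000 to 15000 UMIs that of Timd4 (0.94, edgeR adjusted p = 0.0898). Of the lists without a camera call, periportal and dendritic cell genes were called under 3 alternatives each, clock genes under 2 and T and NK cell genes under 1. The PBS group has 1 section, which is assumed to vary as the APAP sections do. In simulations of this comparison 16.3% of the calls were false on average against the nominal 5%. There 22.9% of 2-fold and 85.5% of 4-fold changes were recovered. The simulations changed 200 of 13615 genes, fewer than were called here, so these shares need not hold for the data.

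Within the APAP sections, spots were compared by a score of 8 periportal genes, the spots of each section being divided by it into 3 equal groups, of which the lowest is the portal-low region and the highest the portal-high region. Loss of hepatocyte RNA lowers this score as distance from the portal tracts does. In APAP the portal-low region had lower pan-lobular hepatocyte genes (median -0.88, against -0.05 in PBS) and no clear rise of pericentral genes (median 0.09), so it does not give position alone. The portal-low region of APAP sections was rich in macrophage, matrix and chemokine transcripts. Gpnmb was 3.08 ± 0.13 log2 units higher there and Trem2 2.5 ± 0.13 (edgeR adjusted p = 1.43e-66 and 2.69e-52). Col1a1 was higher by 2.77 ± 0.13, and Pck1, an enzyme of periportal gluconeogenesis, was lower (-3.13 ± 0.14; edgeR adjusted p = 2.29e-60). The genes with the largest values on the portal-low side were the neuropeptide Nts (3.73), Ccl4 (3.45), Ccr1 (3.27), Cdh17 (3.19), Cthrc1 (3.12), C5ar1 (3.09), Gpnmb and Bcl2a1b (3.06). After Pck1, those on the portal-high side were Clec2h (-2.59), Cyp2b10 (-2.57), Mmd2 (-2.48), Cib3 (-2.26), Defb1 (-2.04), Pigr (-1.95) and Odf3b (-1.94). The 12 periportal genes kept out of the score were all lower on the portal-low side (12 adjusted over the list alone, median -1.54; camera adjusted p = 1.15e-11, and 0.554 with an estimated correlation).

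Macrophage classes lay on the portal-low side of the APAP sections. This held for all 14 pan-macrophage genes (14 adjusted over the list alone, median 1.63), with Lyz2 at 2.72, for 8 of 9 LAM score genes (8 adjusted over the list alone, median 2.5), for 13 of 16 further LAM genes against 1 on the other side (13 and 1 adjusted over the list alone, median 0.92) and for 8 of 10 Kupffer cell genes (8 adjusted over the list alone, median 0.61). Clec4f was 0.37 ± 0.12, Vsig4 0.97 ± 0.12, Timd4 0.62 ± 0.19 and Cd5l 1.04 ± 0.12. Monocyte genes lay there in 9 of 10 (9 adjusted over the list alone, median 2.54; Ccr2 2.88). Neutrophil genes did so in 6 of 6 (6 adjusted over the list alone, median 2.03; S100a8 1.99). Dendritic cell genes did so in 4 of 5 (4 adjusted over the list alone, median 1.33). T and NK cell genes did so in 2 of 5 (2 adjusted over the list alone, median 0.80). Their median log2 ratio was 0.18 in APAP replicate 1 and 0.89 in replicate 2. The fit without replicate 2 gave 2.26, but it filtered genes anew and need not hold the same members. From portal-high to portal-low, Ccl5 went from 52 to 293 and from 67 to 299 UMIs in replicates 1 and 2. Cd3e went from 2 to 5 and from 3 to 3. Chemokine genes lay on the portal-low side in 11 of 15, against 2 on the other side (11 and 2 adjusted over the list alone, median 1.73). Matrix genes did so in 15 of 16 (15 adjusted over the list alone, median 2.05; Lox 2.79). Stellate genes did so in 7 of 10 against 1 (7 and 1 adjusted over the list alone, median 0.84; Pdgfrb 1.44) and central vein endothelial genes in 6 of 6 (6 adjusted over the list alone, median 1.95, and 1.84 in PBS; Wnt2 2.20). Wound-edge hepatocyte genes did so in 10 of 11 (10 adjusted over the list alone, median 1.19). G1/S genes did so in 12 of 17 (12 adjusted over the list alone, median 0.73). G2/M genes did so in 15 of 16 (16 adjusted over the list alone, median 0.90; Mki67 1.29). The p53 targets did so in 10 of 13 against 1 (10 and 1 adjusted over the list alone, median 0.59; Cdkn1a 0.91). Efferocytosis genes did so in 6 of 12 against 2 (7 and 3 adjusted over the list alone, median 0.56). Fetal hepatocyte genes did so in 2 of 5 against 1 (3 and 1 adjusted over the list alone, median 1.12, and 1.72 without APAP replicate 1). The median log2 ratio of the fetal hepatocyte genes was 0.14 in APAP replicate 1 and 1.30 in replicate 2. Each of these lists passed camera, with camera adjusted p from 1.93e-16 for matrix to 0.0465 for fetal hepatocyte genes. With an estimated correlation the camera adjusted p was 0.636 for G1/S, 0.586 for G2/M and T and NK cell, and 0.554 for each of the others.

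Metabolic hepatocyte genes lay on the portal-high side of the APAP sections. Bile acid genes did so in 11 of 12 (11 adjusted over the list alone, median -1.22; Slc10a1 -1.57). Fatty acid oxidation genes did so in 12 of 13 (12 adjusted over the list alone, median -0.87; Ehhadh -1.30). Lipogenesis genes did so in 9 of 10 (9 adjusted over the list alone, median -0.68; Thrsp -1.62). Pan-lobular hepatocyte genes did so in 11 of 12 (11 adjusted over the list alone, median -0.88; Alb -0.90). Acute phase genes did so in 11 of 17 against 2 (11 and 2 adjusted over the list alone, median -0.90) and mitochondrially encoded genes in 10 of 11 (11 adjusted over the list alone, median -0.51). Their camera adjusted p ran from 1.07e-07 for bile acid genes and 2.27e-07 for hepatocyte genes to 0.000413 for mitochondrial genes. With an estimated correlation the camera adjusted p was 0.586 for hepatocyte, 0.599 for lipogenesis and mitochondrial, and 0.554 for bile acid, fatty acid oxidation and acute phase genes. Pericentral genes went both ways in APAP, 8 of 17 on the portal-low side and 3 on the portal-high side (8 and 3 adjusted over the list alone, median 0.09), and did not pass camera: Cyp2e1 was 1.27 ± 0.14 and Glul 0.93 ± 0.18, while Cyp3a11 was -1.57. The other lists without a camera call were, up and down with those adjusted over the list alone in brackets, B and plasma cell 3 and 0 of 5 (3 and 0), sinusoidal endothelial 5 and 2 of 12 (6 and 2), and portal vessel 0 and 2 of 4 (0 and 2). The next were cholangiocyte 0 and 3 of 4 (0 and 4), mesothelial 0 and 0 of 3 (0 and 0), red blood cell 0 and 1 of 5 (0 and 1), NRF2 3 and 5 of 15 (3 and 5), unfolded protein response 3 and 3 of 12 (3 and 3), hypoxia 7 and 4 of 13 (7 and 4), cholesterol 1 and 4 of 15 (1 and 4), sex-linked 0 and 1 of 4 (0 and 1), clock 1 and 5 of 12 (1 and 5) and immediate early 2 and 3 of 9 (2 and 3). In the hypoxia list the glycolytic Pkm had 2.03, and in the NRF2 list Hmox1 had 1.80.

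In the PBS section the same contrast followed the known zonation of pericentral and periportal genes, and some genes of other lists differed too. Pericentral genes were higher on the portal-low side in 14 of 17 cases with none lower (median 2.38), Cyp2e1 by 2.70 ± 0.20 and Glul by 2.38 ± 0.17, and Cyp2f2, a gene of the score, was at -2.47. Bile acid genes were higher on that side in 6 of 12 and lower in none (median 0.50), with Cyp8b1 at 0.86 in PBS and -1.46 in APAP. Periportal genes outside the score were lower there in 8 of 12, acute phase genes in 6 of 17, pan-macrophage genes in 3 of 14, chemokine genes in 3 of 15, red blood cell genes in 3 of 5 and immediate early genes in 2 of 9. Higher there were 3 of 13 fatty acid oxidation genes. Central vein endothelial genes had a median of 1.84 on the portal-low side in PBS, beside 1.95 in APAP. Of these 6 genes 0 were called in PBS and 0 passed the test of the difference between treatments. Of 10 Kupffer cell genes 2 were lower there, Clec4f by -0.75 ± 0.19 and Vsig4 by -0.87 ± 0.26 (edgeR adjusted p = 0.00598 and 0.0376), and the list median was -0.61. Neither of these calls held with library-size scaling (edgeR adjusted p = 0.166 and 0.277), with DESeq2 or in spots of 8000 to 15000 UMIs, and the Cyp8b1 call in PBS ended likewise (edgeR adjusted p = 0.0947 with library-size scaling). In spots of 8000 to 15000 UMIs the PBS values were -0.78 for Clec4f and -1.18 for Vsig4, so these calls ended there without a smaller value. The test of the difference between treatments passed for 15 of 17 pericentral genes, 12 of 12 bile acid genes and 14 of 14 pan-macrophage genes. It also passed for 13 of 16 matrix genes and 6 of 10 Kupffer cell genes.

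**Figure D1:**
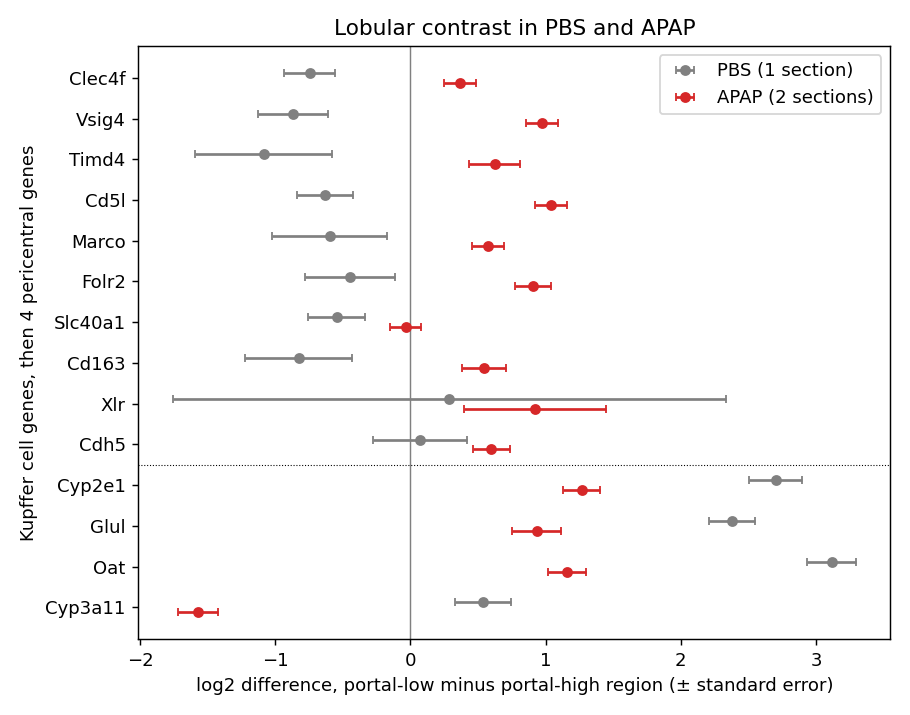
Log2 difference between the portal-low and portal-high regions (x axis, ± standard error) for the 10 Kupffer cell genes and 4 pericentral genes (y axis), in the PBS section (grey, 1 section) and the APAP sections (red, 2 sections). Vsig4 lies at -0.87 in PBS and 0.97 in APAP, and Cyp2e1 at 2.70 and 1.27.

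Over 12506 genes outside the score, edgeR called 2715 genes higher on the portal-low side and 2672 on the portal-high side in APAP, 192 and 128 in PBS, and 706 and 1434 with a higher or lower contrast in APAP than in PBS. Scaling by library size alone shifted the APAP median to 0.42 and split the APAP calls 5680 to 1075 (84.1% higher against 50.4%), DESeq2 called 776 and 1050, and without the section block 1258 and 1050 were called in APAP and 0 differed between treatments with edgeR (1807 at unadjusted p under 0.05; DESeq2, with the block, called 146 and 392). DESeq2 did not call Clec4f or Timd4 in APAP (DESeq2 adjusted p = 0.263 and 0.309), and library-size scaling ended the call of the T and NK cell list (camera adjusted p = 0.0627). In spots with at least 1000 UMIs the T and NK cell list lost its call (median 0.78, camera adjusted p = 0.0533), as did the fetal hepatocyte list (1.07, camera adjusted p = 0.0829). The fetal hepatocyte list also lost it with no filter on low counts (0.77, camera adjusted p = 0.0813). The mitochondrial list lost its call without the section block (camera adjusted p = 0.0504). So did Alb, Cyp2e1, Cyp3a11, Pck1, Slc10a1, Thrsp, Clec4f and Timd4 in APAP (edgeR adjusted p from 0.0634 for Slc10a1 to 0.306 for Cyp3a11) and Cyp2e1 and Cyp2f2 in PBS (edgeR adjusted p = 0.766 and 0.107). A score of the pericentral list minus the portal score ended the APAP calls of Clec4f and Timd4 (edgeR adjusted p = 0.0504 and 0.0764). Of the lists without a camera call, clock genes were called under 3 alternatives, portal vessel and cholangiocyte genes under 2 each and pericentral genes under 1, the score that uses them. With 1 residual degree of freedom the spread of the PBS contrast is taken from the APAP sections. In simulations 5.11% of the calls were false, with 88.3% of 2-fold and 99.6% of 4-fold changes recovered. These simulations changed 200 genes, fewer than were called here, so the shares need not hold for the data.

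Spots in the top 10% of a score of 9 genes of lipid-associated macrophages, called LAM-high, were compared with the other spots of the same section. In the APAP sections these spots held more transcripts of every myeloid list and less of nearly all hepatocyte lists. Lyz2 was 2.16 ± 0.11 log2 units higher in LAM-high spots, Col1a1 2.04 ± 0.11 and Spp1 1.05 ± 0.10 (edgeR adjusted p = 1.01e-88, 2.84e-78 and 5.49e-23), and Alb was lower (-1.29 ± 0.11; edgeR adjusted p = 4.61e-32). Of the LAM-high spots, 72.8% of 125 in APAP replicate 1 and 78.6% of 215 in replicate 2 lay in the portal-low region, and 0.800% and 0.930% in the portal-high region, shares that loss of hepatocyte RNA can shift as well as position. The score is continuous: 3.93% and 3.25% of the spots in APAP replicates 1 and 2 lay within 0.1 of the threshold, against 94.4% in the PBS section, where most spots had no UMI of the score genes. The median over LAM-high spots was 13.3 counts per 10000 UMIs of Kupffer cell genes in APAP replicate 1 and 12.7 in replicate 2, against 5.26 and 5.32 over the other spots, and 812 and 1103 of pan-lobular hepatocyte genes against 1646 and 1850.

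**Figure D2:**
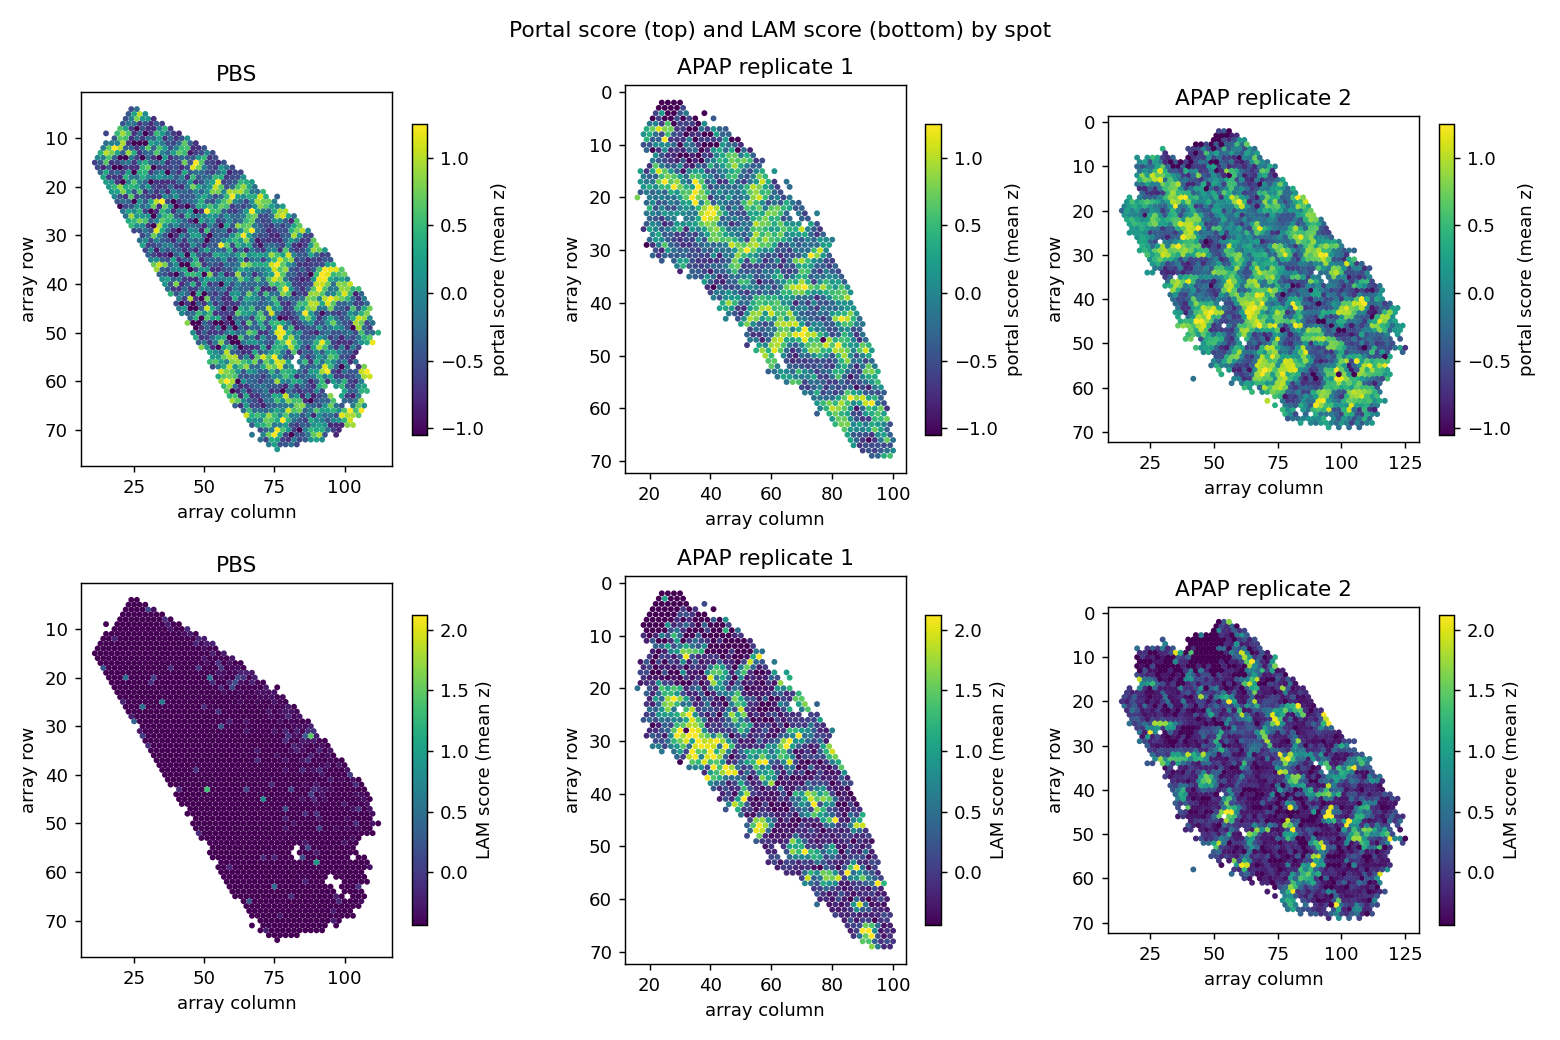
Tissue spots of each section at their array column (x axis) and array row (y axis), coloured by the portal score (top) and by the LAM score (bottom), both in mean z units over the score genes on deposited counts. High LAM scores lie mostly in spots of low portal score in the APAP sections, where 72.8% and 78.6% of the LAM-high spots lie in the portal-low region, and the PBS section has lower depth.

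The genes with the largest values in LAM-high spots, outside the score, were the collagenase Mmp13 (2.95, and 1.91 without APAP replicate 1), Dclk1 (2.85), F13a1 (2.51), Adam8 (2.43), Sirpb1c (2.43), Lat2 (2.41), Slfn1 (2.39) and Chil3 (2.38), and the lowest values were those of Cyp2b10 (-3.08), Pck1 (-2.59), Cib3 (-2.58), Lin7a (-2.44, and -3.18 without APAP replicate 2), Clec2h (-2.43), Etnppl (-2.34), Slc30a10 (-2.33) and Sdr9c7 (-2.29). LAM genes outside the score were higher in 13 of 16 and lower in 2 (13 and 2 adjusted over the list alone, median 0.81), with Lpl at 1.83, Ctsb at 1.40 and Cd9 at 0.67. Kupffer cell genes were higher in 7 of 10 (7 adjusted over the list alone, median 0.65), with Folr2 at 1.18, Cd5l at 0.92, Vsig4 at 0.86 and Clec4f at 0.36. Timd4 had 0.32 ± 0.22 and did not pass (edgeR adjusted p = 0.247). Timd4 passed with library-size scaling and in the top 20% (0.76 and 0.57; edgeR adjusted p = 0.00519 and 0.00726) and under no other alternative. Pan-macrophage genes were higher in 14 of 14 (14 adjusted over the list alone, median 1.60; Adgre1 1.57). Monocyte genes were higher in 10 of 10 (10 adjusted over the list alone, median 2.16; Ccr2 2.09). Neutrophil genes were higher in 7 of 8 (7 adjusted over the list alone, median 1.93; S100a8 1.90) and dendritic cell genes in 4 of 6 (4 adjusted over the list alone, median 1.58). Chemokine genes were higher in 11 of 15 and lower in 2 (11 and 2 adjusted over the list alone, median 1.35). Matrix genes were higher in 15 and lower in 1 of 16 (15 and 1 adjusted over the list alone, median 1.66; Fbln2 2.06). Stellate genes were higher in 7 and lower in 1 of 10 (7 and 1 adjusted over the list alone, median 0.54). Central vein endothelial genes were higher in 5 of 6 (5 adjusted over the list alone, median 1.25). Wound-edge genes were higher in 8 of 12 (8 adjusted over the list alone, median 1.19). Efferocytosis genes were higher in 6 and lower in 3 of 12 (6 and 3 adjusted over the list alone, median 0.43). G1/S genes were higher in 10 of 17 (11 adjusted over the list alone, median 0.52) and G2/M genes in 9 of 16 (10 adjusted over the list alone, median 0.47; Mki67 0.59). The sections differed for these 2 lists: the median log2 ratio of G1/S and G2/M genes was 0.15 and 0.016 in APAP replicate 1 and 0.85 and 0.90 in replicate 2. Each of these lists passed camera (camera adjusted p from 1.93e-22 for pan-macrophage to 0.0240 for efferocytosis genes). With an estimated correlation the camera adjusted p was 0.568 for stellate, 0.532 for efferocytosis, 0.651 for G1/S and 0.685 for G2/M genes and 0.526 for each of the others.

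Hepatocyte lists were lower in LAM-high spots of the APAP sections. All 12 pan-lobular genes were lower (12 adjusted over the list alone, median -1.27; Fabp1 -1.95), as were all 8 genes of the portal score (8 adjusted over the list alone, median -1.84; Cyp2f2 -2.09). So were 11 of 12 periportal genes (11 adjusted over the list alone, median -1.31). So were all 12 bile acid genes (12 adjusted over the list alone, median -1.59). So were all 15 cholesterol genes (15 adjusted over the list alone, median -0.90). So were 12 of 13 fatty acid oxidation genes (12 adjusted over the list alone, median -1.0). So were 9 of 10 lipogenesis genes (9 adjusted over the list alone, median -1.08). So were 14 of 17 acute phase genes with 0 higher (14 lower and 1 higher adjusted over the list alone, median -1.22) and 10 of 11 mitochondrial genes (10 adjusted over the list alone, median -0.62). Pericentral genes were lower in 12 of 17 and higher in 2 (12 and 2 adjusted over the list alone, median -1.11), with Cyp2e1 at -0.88 and Glul at 1.12, and NRF2 targets were lower in 10 of 15 and higher in 1 (10 and 1 adjusted over the list alone, median -0.60), the higher one being Hmox1 (2.00 ± 0.11), which degrades haem and is expressed by macrophages. Each of these lists passed camera (camera adjusted p from 9.98e-17 for pan-lobular to 0.00650 for NRF2 genes). At an estimated correlation the camera adjusted p was 0.532 for pan-lobular, fatty acid oxidation and acute phase, 0.538 for cholesterol, 0.568 for NRF2 and 0.526 for the other 6 lists. The lists without a camera call were, higher and lower with those adjusted over the list alone in brackets, T and NK cell 4 and 0 of 8 (4 and 0), B and plasma cell 3 and 0 of 6 (3 and 0), sinusoidal endothelial 2 and 3 of 12 (2 and 3), portal vessel 0 and 0 of 5 (0 and 0), cholangiocyte 0 and 1 of 6 (0 and 1), mesothelial 1 and 0 of 4 (1 and 0), red blood cell 0 and 4 of 5 (0 and 5; median log2 ratio 0.28 in APAP replicate 1 and -1.09 in replicate 2), p53 4 and 1 of 13 (4 and 1; Cdkn1a 0.45), unfolded protein response 1 and 5 of 12 (1 and 6), hypoxia 6 and 5 of 13 (6 and 5), fetal hepatocyte 1 and 1 of 6 (1 and 1), sex-linked 0 and 1 of 4 (0 and 1), clock 0 and 5 of 12 (0 and 6) and immediate early 4 and 3 of 9 (4 and 3; 0.53 and -0.15). In the sinusoidal list Stab1 was higher (1.22) and Clec4g lower (-1.11).

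Over 13155 genes outside the score, edgeR called 2444 genes higher and 2855 lower in LAM-high spots of the APAP sections, 9 higher and 0 lower in those of the PBS section (622 at unadjusted p under 0.05; DESeq2 called 2 and 0), and 457 and 1567 with a higher or lower contrast in APAP than in PBS. Scaling by library size alone shifted the APAP median to 0.45 and split the APAP calls 5192 to 1349 (79.4% higher against 46.1%), DESeq2 called 904 and 1402, within the portal-low region alone 1114 and 1530 were called, and without the section block 0 differed between treatments with edgeR (1674 at unadjusted p under 0.05; DESeq2, with the block, called 95 and 756). DESeq2 did not call Clec4f, Mki67 or Cdkn1a (DESeq2 adjusted p = 0.0696, 0.151 and 0.364), and library-size scaling ended the calls of the G2/M and NRF2 lists (camera adjusted p = 0.0539 and 0.192). Within the portal-low region 6 lists lost their call: G1/S (median 0.27, camera adjusted p = 0.124), G2/M (0.14, 0.460), central vein endothelial (0.37, 0.221), stellate (0.49, 0.0707), efferocytosis (0.15, 0.0579) and the portal score (-0.39, 0.0749). Col1a1 (1.25), Cyp2b10 (-1.26), Clec4f (0.12) and Mki67 (0.18) lost their calls there too (edgeR adjusted p = 0.0768, 0.150, 0.430 and 0.422). Over all alternatives the calls of Cdkn1a, Mki67 and Clec4f ended under 8, 6 and 5. Without the section block those of Ccr2, Slfn1, Pck1, Spp1 and Cyp2e1 ended (edgeR adjusted p = 0.0594, 0.0658, 0.0682, 0.123 and 0.451). With the score on thinned spots Glul fell to 0.46 and lost its call (edgeR adjusted p = 0.0789). The G1/S call also ended without the section block (camera adjusted p = 0.0743). The G2/M call ended with thinned libraries and with the score without Lgals3 and Cd63 (camera adjusted p = 0.0616 and 0.0911). The central vein call ended in spots of 8000 to 15000 UMIs (camera adjusted p = 0.0587). The stellate call ended in the top 5% (camera adjusted p = 0.0512). The efferocytosis call ended with no filter on low counts (camera adjusted p = 0.0667). The NRF2 call ended in the top 20%, with the score without Lgals3 and Cd63 and with the score on thinned spots (camera adjusted p = 0.247, 0.0846 and 0.0995). At least 1 UMI of Trem2 or Gpnmb ended the calls of the pericentral list (median -0.00421, camera adjusted p = 0.682) and the mitochondrial list (-0.0806, camera adjusted p = 0.330). With LAM-high taken as at least 1 UMI of Trem2 or Gpnmb, Cyp2e1 turned to 0.12 and the NRF2 list median came to -0.0202 with its camera direction turned, and within the portal-low region Cdkn1a turned to -0.0543, Timd4 to -0.0279 and Etnppl, a gene of the portal score, to 0.0211. Of the lists without a camera call, red blood cell genes were called under 4 alternatives (camera adjusted p from 2.10e-06 with at least 1 UMI of Trem2 or Gpnmb to 0.0263 in spots of 8000 to 15000 UMIs). Unfolded protein response genes were called under 3, and T and NK cell, p53, hypoxia and clock genes under 1 each. Random classes of 10% of the spots, drawn 5 times, gave up to 18 calls in APAP, 34 in PBS and 57 for the difference. The 34, all lower, and the 57, all higher, came from 1 draw. The other draws gave at most 1 call in PBS and 3 for the difference. The PBS class is mainly one of depth (median 12826.5 UMIs in LAM-high spots against 2505 in the others). In simulations 4.08% of the APAP calls were false, with 72.6% of 2-fold and 95.4% of 4-fold changes recovered. These simulations changed 200 genes, fewer than were called here, so the shares need not hold for the data.

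To compare shares of spots at equal depth, each spot was thinned to 1000 UMIs, which left out 104 PBS spots and 58 and 51 spots of APAP replicates 1 and 2. After thinning, Trem2 was seen in 0.178% of PBS spots (95% exact binomial interval 0.0367 to 0.519) and in 7.08% (5.71 to 8.68) and 5.64% (4.70 to 6.71) of spots of APAP replicates 1 and 2; without thinning the shares were 1.28%, 40.6% and 34.0%. Gpnmb was seen in 0.119% of PBS spots and in 12.6% and 9.45% of APAP spots, and unthinned in 0.726%, 47.2% and 41.5%. Clec4f was seen in 6.70%, 14.2% and 13.3% of spots, and unthinned in 27.8%, 67.1% and 67.1%. Cyp2e1 was seen in 61.0%, 12.9% and 27.5%, and unthinned in 84.0%, 58.0% and 77.5%. The share of thinned spots above the 99th percentile of the PBS LAM score was 0.830% in PBS (14 of 1686; 0.455 to 1.39), 30.9% in APAP replicate 1 (375 of 1214; 28.3 to 33.6) and 22.8% in APAP replicate 2 (486 of 2127; 21.1 to 24.7). Spots are not replicates, so these intervals cover counting error only, and free RNA can place UMIs in spots without the cells that made it.

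Macrophage and matrix transcripts declined with distance from LAM-high spots in both APAP sections. Kupffer cell genes summed to 14.35 counts per 10000 UMIs in LAM-high spots, 9.23 in spots 1 step away on the grid, 5.85 at 2 steps and 5.13 at 3 or more steps in APAP replicate 1, and to 14.07, 8.14, 5.53 and 5.45 in replicate 2. Matrix genes went from 93.2 to 25.7 counts per 10000 between LAM-high spots and spots 3 or more steps away in replicate 1 and from 97.1 to 21.4 in replicate 2, and monocyte genes from 9.15 to 0.832 and from 4.78 to 0.708. Pan-lobular hepatocyte genes rose from 823 to 1698 and from 1147 to 1864 over the same distance. Across spots, the rank correlation of the pan-macrophage score with the LAM score was 0.77 and 0.67 in APAP replicates 1 and 2 and 0.23 in PBS, that of the Kupffer cell score 0.53, 0.39 and 0.21, and that of the hepatocyte score -0.70, -0.53 and 0.20. On thinned spots the pan-macrophage values were 0.49, 0.39 and -0.03, the Kupffer cell values 0.20, 0.14 and -0.01, and the hepatocyte values -0.54, -0.40 and -0.02. These are correlations across spots of 1 section, which are not independent, and carry no test.

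**Figure D3:**
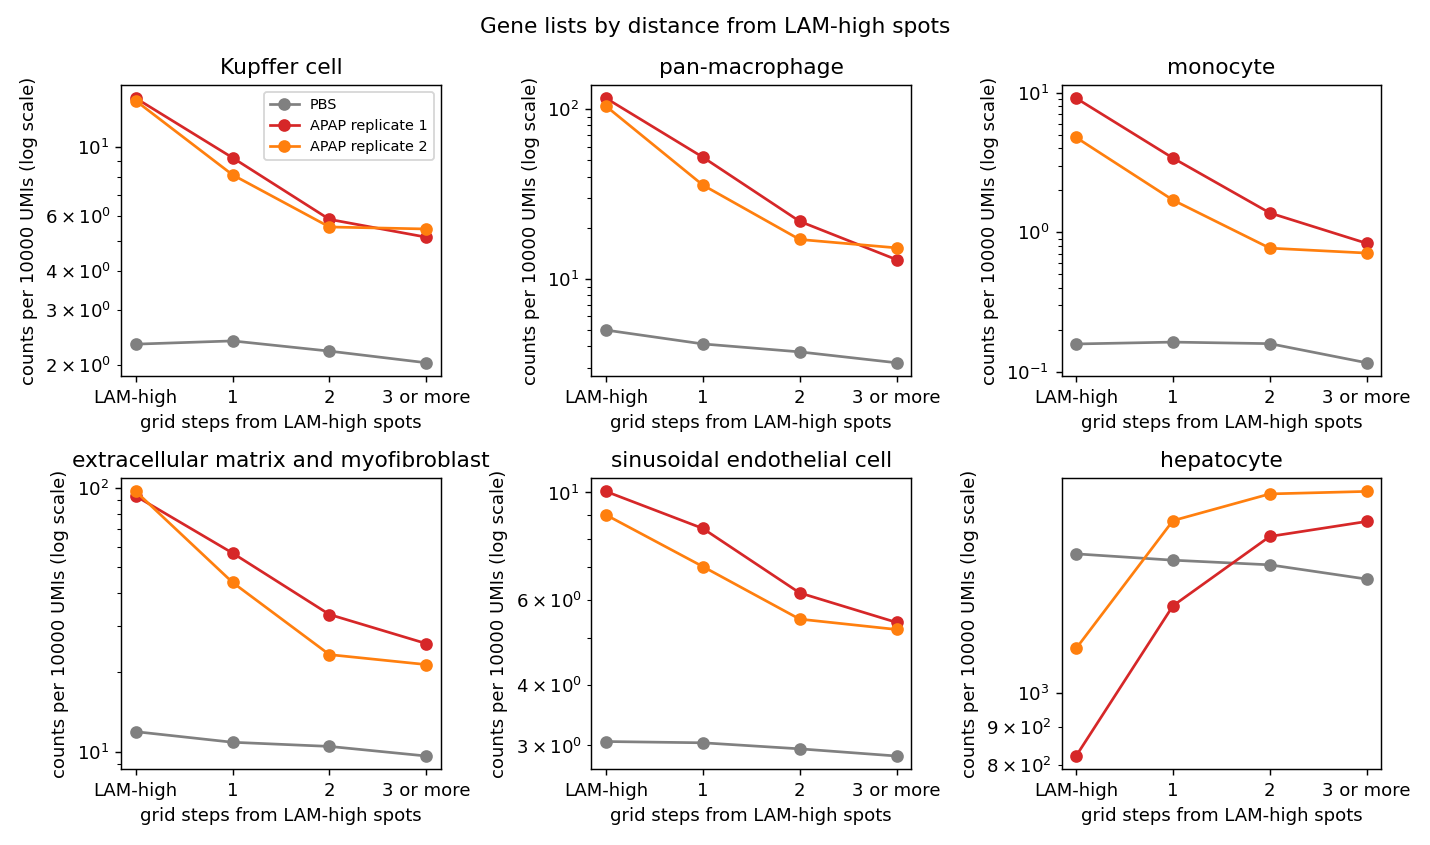
Summed counts per 10000 UMIs (y axis, log scale) of 6 gene lists in LAM-high spots and in spots 1, 2 and 3 or more grid steps away (x axis), for each section (lines), pooled over the spots of a ring and without error bars. Kupffer cell genes fall from 14.35 to 5.13 in APAP replicate 1 and from 14.07 to 5.45 in replicate 2, while the PBS line is nearly flat at 2.33 to 2.03.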

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

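The comparisons with genes of other cell types were chosen after the result had been seen, and the window of 8000 to 15000 UMIs per spot was added after the depths were known; the prediction for that window was written before its values were computed.

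The contrast between the portal-low and portal-high regions differed between treatments for 706 genes that were relatively higher in APAP and 1434 that were relatively lower (edgeR test of the difference, adjusted p under 0.05). Among genes of the macrophage lists the difference, APAP minus PBS on the log2 scale, was 2.52 ± 0.67 for Trem2, 4.0 ± 0.28 for Spp1, 0.78 ± 0.24 for Cd9 and 2.48 ± 0.41 for Adgre1. The PBS section held 358 UMIs of Spp1 in the portal-high and 40 in the portal-low region. The Spp1 difference thus rests in part on a portal-high side in PBS, and the cells that made these transcripts were not identified. The difference was 2.28 ± 0.37 for the collagen gene Col1a1, -1.44 ± 0.23 for Cyp2e1 and -1.45 ± 0.25 for Glul. It was 5.10 ± 0.84 for the neutrophil gene S100a8, whose PBS side rests on 2 UMIs in the portal-low and 22 in the portal-high region, a ratio of 0.113 (95% counting interval 0.0128 to 0.458). DESeq2 did not call the differences of Clec4f, Timd4 and Cd9 (DESeq2 adjusted p = 0.0517, 0.270 and 0.380) and gave no adjusted p for S100a8. In spots of 8000 to 15000 UMIs edgeR did not call Cd9 (1.26; edgeR adjusted p = 0.103), Adgre1, Timd4, S100a8 or Trem2. There the PBS portal-high and portal-low regions held 4 and 4 UMIs of Adgre1, 6 and 5 of Timd4, 1 and 1 of S100a8 and 1 and 0 of Trem2, too few to measure a difference. Cd9 was not called in spots with at least 3000 UMIs (edgeR adjusted p = 0.0653) nor Trem2 in thinned libraries (edgeR adjusted p = 0.0673). The Timd4 call ended under 8 alternatives in all.

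The portal contrast of Kupffer cell genes had a median of -0.61 in PBS, where 2 of 10 genes passed (Clec4f and Vsig4, whose calls ended under 7 and 10 alternatives), and of 0.61 in APAP, where 8 passed; the difference was 1.11 ± 0.22 for Clec4f, 1.84 ± 0.28 for Vsig4, 1.71 ± 0.53 for Timd4 and 1.67 ± 0.24 for Cd5l, and 6 of 10 genes passed its test. Low depth of the PBS section as the whole cause is argued against, since in spots of 8000 to 15000 UMIs the median difference over 9 of these genes was 1.85 (all 9 above 0), against 1.26 over 10 genes in all spots, although 3 of the 9 passed there (Clec4f, Vsig4 and Cd5l) and the PBS regions held 3 to 72 UMIs of each gene. A loss of hepatocyte RNA in portal-low spots that raises every other cell type alike is also argued against, because the median difference over 25 genes was 0.02, with -0.03 for sinusoidal endothelial, -0.27 for portal vessel, 0.20 for cholangiocyte and 0.70 for B cell genes (two-sided permutation p over genes, which are not independent replicates, = 0.00112). With central vein, stellate, mesothelial and T and NK cell genes added the median over 49 genes was 0.21 (two-sided permutation p = 0.00682). Over the 38 of these with at least 10 UMIs in PBS, none of them mesothelial, it was 0.18 (two-sided permutation p = 0.000800). The added lists had medians of 0.04 for central vein, 0.35 for stellate, 1.21 for T and NK cell and 5.35 for mesothelial genes. The last 2 were near or above the Kupffer cell median of 1.26, though most of their genes had few UMIs in PBS. Kupffer cell genes thus did not stand above every other list. The comparison also supposes that the other cell types were not themselves lost from portal-low spots of APAP sections, which was not tested. A loss of hepatocyte RNA joined by a fall of those cells is not excluded by it. A portal-low class that stands for position in PBS and also for loss of hepatocyte RNA in APAP stays open, as does ordinary variation between control sections, since there is 1 PBS section, and without the section block edgeR called 0 differences over all genes (1807 at unadjusted p under 0.05; DESeq2, with the block, called 146 and 392); the place of the cells and their transcripts per cell were not separated by any test.

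The contrast between LAM-high and other spots differed between treatments for 457 genes that were relatively higher in APAP and 1567 that were relatively lower. In PBS the LAM-high class is mainly one of depth (median 12826.5 UMIs against 2505). Of the PBS spots, 94.4% lay within 0.1 of the threshold. The difference thus sets a LAM class in APAP beside a depth class in PBS. The difference on the log2 scale was -0.63 ± 0.21 for Spp1, 0.96 ± 0.21 for Cd5l, 1.38 ± 0.38 for Adgre1, 2.05 ± 0.69 for S100a8 and 1.08 ± 0.31 for Col1a1. It was -0.97 ± 0.18 for Cyp2e1, 1.33 ± 0.22 for Glul, -1.97 ± 0.18 for Cyp2f2 and -1.34 ± 0.18 for Alb. These calls ended under 11 alternatives for Spp1 (4 with the sign changed), 9 for S100a8, 9 for Col1a1, 8 for Adgre1, 6 for Cd5l, 3 for Cyp2e1 (1 with the sign changed), 3 for Cyp2f2, 3 for Glul and 2 for Alb. In spots of 8000 to 15000 UMIs the Adgre1 difference was 0.18 (edgeR adjusted p = 0.975) on 3 UMIs in LAM-high and 10 in other PBS spots, and that of S100a8, on 1 and 2 UMIs, was not called. Within the portal-low region the Cd5l difference was 0.0672 (edgeR adjusted p = 0.975), and in thinned libraries the Col1a1 difference was 0.63 (edgeR adjusted p = 0.606). Random classes of 10% of the spots, drawn 5 times, gave up to 34 calls in PBS and up to 57 for the difference, both from 1 draw. The other draws gave at most 1 and 3.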

How the results depend on the processing

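The spots of 8000 to 15000 UMIs and the LAM-high spots within the portal-low region were chosen after seeing the data; all other alternatives were planned. Low depth of the PBS section, 1 PBS section and 1 residual degree of freedom limit every comparison with PBS. No paired analysis of APAP against PBS sections was possible with 1 PBS section, while the region fits compared classes within each section. Without either APAP section no residual degree of freedom is left, so values carry no test: 3274 of 3274 and 3270 of 3270 called genes kept their direction in APAP versus PBS, 5278 of 5284 and 5300 of 5316 in the portal contrast, and 5217 of 5227 and 5240 of 5254 in the LAM-high contrast, without replicates 1 and 2. Genes called by both edgeR and DESeq2 had the same direction: 1786 of the 1868 DESeq2 calls were shared in APAP versus PBS, 1822 of 1826 in the portal contrast and 2306 of 2306 in the LAM-high contrast. Of the gene values over all alternatives, 2561 held, 151 lost the call, 17 gained it, 94 had no test and moved, and 9 reversed. A value held if it kept direction and side of the threshold or, without a test, moved by less than its standard error. For list values the counts were 1605, 26, 28, 58 and 2. Lists not called at first were checked for the call alone, not for direction. Of the shares of spots 4 stayed within their interval and 50 moved. Except where a cause is given, the cause was not tested.

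Counts are higher and then lower unless said. DESeq2 gave 1193 and 675 for APAP versus PBS. It gave 776 and 1050 for the portal contrast in APAP, 50 and 32 in PBS, and 146 and 392 for its difference. For the LAM-high contrast it gave 904 and 1402 in APAP, 2 higher in PBS, and 95 and 756 for its difference. DESeq2 gave no adjusted p to 5095 of 12506 genes for the portal difference and to 8674 of 13155 for the LAM-high difference. In the portal contrast in PBS 4125 genes had none, and in the LAM-high contrast in APAP 2042. A gene without one counts as not called, and a call lost this way counts as ended. Library-size scaling gave 573 lower for APAP versus PBS, 5680 and 1075 for the portal contrast in APAP, 113 and 53 in PBS, 443 lower for its difference, 5192 and 1349 for the LAM-high contrast in APAP, 4 higher in PBS, and 1334 and 716 for its difference. A filter of at least 10 CPM in 2 libraries, which tests fewer genes, gave 989 and 768 for APAP versus PBS, 77 and 52 for the portal contrast in PBS, and 465 and 910 for its difference. With no filter 1 gene was lower in the LAM-high contrast in PBS. Libraries thinned to the smallest gave 118 and 65 for the portal contrast in PBS, 424 higher for its difference, 3 higher for the LAM-high contrast in PBS and 163 higher for its difference.

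Without the section block edgeR gave 1258 and 1050 for the portal contrast in APAP, 9 and 2 in PBS and 0 and 0 for its difference (1807 at unadjusted p under 0.05; DESeq2, with the block, 146 and 392). It gave 1228 and 1405 for the LAM-high contrast in APAP, 0 higher in PBS (220 at unadjusted p under 0.05; DESeq2 2) and 0 and 0 for its difference (1674 at unadjusted p under 0.05; DESeq2 95 and 756). Spots of 8000 to 15000 UMIs, which are fewer, gave 1595 lower for the portal contrast in APAP, 53 and 26 in PBS, 128 and 399 for its difference, 1589 higher for the LAM-high contrast in APAP, 2 and 2 in PBS, and 83 and 482 for its difference. There the Cyp2e1 difference was 0.0489 (-0.97 over all spots). Within the portal-low region the LAM-high contrast gave 1114 and 1530 in APAP with 9 lists higher, 1 and 4 in PBS, and 30 and 537 for the difference. Cdkn1a turned to -0.0543 there (from 0.45), Timd4 to -0.0279 (from 0.32), Etnppl, a gene of the portal score, to 0.0211 (from -2.34), and the Spp1 difference to 0.59 (from -0.63).

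With the LAM score on thinned spots the contrast gave 1494 higher in APAP, 0 higher in PBS with edgeR (477 at unadjusted p under 0.05; DESeq2, on the score as first taken, 2), 106 and 693 for the difference, and 0.46 for the Spp1 difference. The PBS class of that score held many tied spots taken in spot order, so its PBS calls and differences decide little. Spots with at least 1 UMI of Trem2 or Gpnmb gave 17 and 29 in PBS, 16 and 27 for the difference, 0.27 for the Spp1 difference, 0.12 for Cyp2e1 (from -0.88) and -0.0202 for the NRF2 list, whose camera direction turned (from -0.60). The score without Lgals3 and Cd63 gave 1 higher in PBS and 0.50 for the Spp1 difference. In PBS the top 20% gave 1 higher, the top 5% 3 lower (226 higher for the difference), spots with at least 3000 UMIs 1 lower, and a score of summed counts 5 lower and, for the portal contrast, 82 lower. The pericentral list minus the portal score gave 212 lower in PBS and 457 higher for the difference. With haemoglobin genes left out the red blood cell list turned to -1.11 (from 3.50), because Alas2 alone was left.

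Camera with an estimated correlation called 0 lists higher and 0 lower in each of the 3 comparisons. The preset correlation gave 17 and 6, 18 and 7, and 14 and 11. The correlation was estimated on 1 residual degree of freedom. In APAP versus PBS the G2/M and stellate lists, at 3.5e-45 and 0.00106 with the preset correlation, both had 0.604 (camera adjusted p). This alternative had little room to call any list, so its 0 calls do not decide whether a list changed. Fry rested on the same fits with 1 residual degree of freedom. Directional fry called 0 and 0 for APAP versus PBS, 0 and 0 for the portal contrast, and 1 (pan-macrophage, fry adjusted p = 0.00463) and 0 for the LAM-high contrast; mixed fry called 0, 0 and 1 (bile acid, fry adjusted p = 0.0328). Among random lists matched on expression, the G2/M median of APAP versus PBS lay at percentile 100 and the pericentral median at 0. In the portal contrast in APAP matrix lay at 100 and bile acid at 0. T and NK cell lay at 67.3, mitochondrial at 42.5 and pan-lobular at 85.0 there. In the LAM-high contrast pan-macrophage lay at 100, mitochondrial at 39.9 and pan-lobular at 69.4. Camera called all of these, but values from 39.9 to 85.0 are not extreme. Matched genes were drawn from neighbouring expression ranks and could be members of the list itself. For pan-lobular genes, which rank near the top, such a percentile compares them with other highly expressed genes. It does not decide whether they fell. The share of spots above the LAM threshold was 45.5% and 36.9% in APAP replicates 1 and 2 when not thinned, and 1.96% in PBS, 43.2% and 35.2% at the 95th percentile (0.830%, 30.9% and 22.8% as first taken).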

Other observations

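The comparisons of Kupffer cell genes with genes of other cell types, and the ratio between the APAP sections, were chosen after the results had been seen, and the window of 8000 to 15000 UMIs was added after the depths were known; the predictions for that window were written before its values were computed.

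Over LAM-high spots the median was 115 and 104 counts per 10000 UMIs of pan-macrophage genes in APAP replicates 1 and 2, against 14.7 and 14.9 over the other spots, and 86.2 and 96.8 of matrix genes against 27.6 and 23.1. Sinusoidal endothelial genes had medians of 9.94 and 8.67 against 6.09 and 5.39. In the PBS section the pan-macrophage medians were 3.56 and 2.24 and the matrix medians 11.4 and 9.67. The 9 genes called higher in LAM-high spots of the PBS section are not given singly. With the score taken on thinned spots edgeR called 0 (477 at unadjusted p under 0.05). There 33 of 1686 PBS spots lay above the 95th percentile of the PBS score, since many scores were tied. The PBS top 10% thus held many tied spots taken in spot order, so its 0 calls do not bear on the 9 genes. DESeq2, on the score as first taken, called 2. Random classes of the same size gave up to 34 calls, all of them lower and from 1 draw. The other draws gave at most 1 call. With 5 draws, none matched on depth, the random classes do not decide whether the 9 higher genes exceed chance.

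Kupffer cell genes were higher in whole APAP sections (median log2 fold change 1.40, 9 of 10 genes called). In spots of 8000 to 15000 UMIs in every section the median was 1.58, with all 10 above 0 and 6 passing (Clec4f, Cd163, Timd4 and Xlr had edgeR adjusted p = 0.0702, 0.0836, 0.0898 and 0.400), so low depth of the PBS section is not a likely cause of the whole difference. A lower hepatocyte share that raised every other cell type alike stays open: the median was 0.41 over 34 genes of sinusoidal and portal vessel endothelium, cholangiocytes and B cells (two-sided permutation p over genes, which are not independent replicates, = 0.00183), but 0.80 over 62 genes with central vein, stellate, mesothelial and T and NK cell genes added (0.0816). The list medians were -0.0598 for cholangiocyte, 0.15 for B cell, 0.64 for portal vessel, 0.73 for sinusoidal, 1.00 for T and NK cell, 1.20 for stellate, 1.41 for central vein and 1.79 for mesothelial genes. Cdh5, 1 of the 10 Kupffer cell genes, is also expressed by endothelial cells, and more Kupffer cells, more of these transcripts per cell, and their expression by other macrophages were not separated by any test here.

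Mitochondrially encoded transcripts were lower in whole APAP sections (median log2 fold change -1.39 over 11 genes), and took 2.07% of the UMIs in PBS against 1.42% and 0.693% in APAP replicates 1 and 2. In spots of 8000 to 15000 UMIs the median was -0.99, so low depth of the PBS section is unlikely to be the whole cause. Ordinary differences between sections and an effect of APAP cannot be told apart: the median log2 ratio of APAP replicate 1 over replicate 2 was 0.67, beside 1.10 and 1.76 for PBS over replicates 1 and 2, and there is 1 PBS section. Tissue quality and the time to freezing were not given in the sources used here.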
